A study of Mus musculus with 6 samples.

How the data were processed

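Gene expression was measured on 6 single-colour Affymetrix arrays hybridised with biotin-labelled total RNA from RW4 cells, a line of mouse embryonic stem cells. Per the labels, the arrays formed 3 groups of 2: untreated cells, cells given 1 µM 4-hydroxytamoxifen (4OHT), and cells given 1 µM Shld1. Per the labels' protocols, the cells were grown on gelatin with calf and fetal bovine serum at 10% each and leukemia inhibitory factor at 1000 U/mL, and RNA was isolated with a column kit and treated with DNase. The length of the treatments is not given in the sources used here. The labels name the arrays of a group duplicates and do not say whether they came from separate cultures, so p-values measure the spread between these samples, which may be technical.

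The deposited table held 1 value per probe set and array, for 35556 probe sets, with no missing values. The deposited values were on a log2 scale, as read from their range. Their distributions were similar but not the same on every array, with SDs of 2.24 to 2.35. The method of background correction, summarization and normalization is not given in the sources used here. The submitters' processing notes name limma 3.14 without its role. Array medians ran from 4.20 to 4.32. The values were used as deposited, with no further normalization in the primary analysis.

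Probe sets were named from the platform annotation supplied with the table. Of the 35556 probe sets, 21789 had exactly 1 gene symbol, 1621 had several and 12146 had none in that annotation; only those with 1 symbol were named. Of the 21789, 21698 matched a current mouse gene record by Entrez identifier, and the others kept the symbol of the annotation. The gene table was used for names only, and no coordinates are printed because the sources used here name no build for the array. Where a gene had more than 1 probe set (999 genes), the brightest over all 6 arrays was used. This left 19938 genes.

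Each comparison was fitted with limma 3.58.1 in R 4.3.3, with a mean per group over all 6 arrays, empirical Bayes moderation without an intensity trend, and two-sided tests adjusted by the Benjamini-Hochberg method over the 19938 genes. The fit had 3 residual degrees of freedom, to which the moderation added 6.77. Groups of 2 arrays limit the precision: the median standard error of a log2 difference was 0.160 and the median half-width of its 95% interval 0.357. An exact two-sided permutation test of 2 arrays against 2 cannot give a p below 0.333, so none was used. Values are means ± SD of log2 signal, n = 2 per group.

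Before the data were examined, 33 gene lists were fixed (states and cell types, pathways, and technical classes of transcripts), as were the tests and the rule for naming genes. That rule takes, per comparison, up to 10 genes past the threshold with the largest rise and 10 with the largest fall, filled up with those of the largest moderated statistic where fewer pass. It adds Esr1, Esr2, Fkbp1a, Pou5f1, Sox2, Nanog and Klf4, and up to 3 members per list. Lists were tested with camera from limma at a preset correlation of 0.01, adjusted over the 33 lists. Camera with a correlation estimated per list and the rotation test fry were run as alternatives. Within a list, genes were also adjusted over the list alone.

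The mean signal of 1015 olfactory receptor genes, which stem cells are not known to use, served as a view of background. Its 95th percentile was 3.73, and 12815 of the 19938 genes lay above it. This level was set after the data were seen and filtered nothing.

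The steps were tested on simulated data for 4OHT against untreated, in 20 runs of 19938 genes with 200 changed. The limma step recovered 5.8% of genes changed 1.5-fold, 75.1% at 2-fold and 98.5% at 3-fold, with 7.55 false calls per run. These shares hold for 200 changed genes, since the adjustment is laxer when many genes change. With few changed genes a smaller share would be recovered. In the data, Abca1 differed 2.005-fold between 4OHT and untreated and had adjusted p = 0.96 (limma). It made 0 calls in an unchanged group. Camera found a list of 20 genes shifted by -0.3 in 100% of runs at either correlation setting, counted at unadjusted p under 0.05. The simulated genes varied independently of one another and had the same spread in every group. On the arrays, the SD of the replicate difference was 0.216 in untreated cells, 0.264 with 4OHT and 0.318 with Shld1. The simulated shares may therefore not hold for these groups.

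Further alternatives were other moderation, quantile normalization, centring on the 75th percentile, leaving out the dimmest 40% of genes, testing every probe set, averaging probe sets, fitting only the groups compared, array weights, the replicate number as a block, a minimum of 1.5-fold, and leaving out each array in turn. Cyclic loess normalization, leaving out 4OHT replicate 1 together with Shld1 replicate 2, and correlating the agents' differences each against its own untreated array were added after seeing the data. Figures were drawn with matplotlib 3.10.9.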

Results

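RW4 mouse embryonic stem cells were profiled without treatment, with 1 µM 4OHT or with 1 µM Shld1, with 2 arrays per group. 4OHT is a ligand of the estrogen receptor, and its use here was tied by the labels to an ERT2 induction system, in which a mutated estrogen receptor domain responds to the drug. Shld1 is a small ligand that stabilises proteins fused to a destabilised FKBP domain, and the labels tied it to an FKBP induction system. The labels do not say whether the cells carried such a fusion. The series asks what either inducer does to gene expression in these cells.

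The arrays were closely alike whatever their group. Across the 19938 genes tested, Pearson's r between arrays of the same group averaged 0.992, with a range from 0.989 to 0.995, and between arrays of different groups it also averaged 0.992; genes are not independent replicates. The SD of the log2 difference was 0.266 on average within groups and 0.268 between groups. Both 4OHT replicate 1 and Shld1 replicate 2 had a narrower range of signals than the rest. Their SDs over all 35556 probe sets were 2.29 and 2.24, against 2.33 to 2.35 on the other 4 arrays. The untreated arrays differed from each other by more than 2-fold at 10 genes, the 4OHT arrays at 30 and the Shld1 arrays at 108.

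The 4OHT and untreated arrays overlapped for the core stem cell factors Pou5f1, Sox2 and Nanog. Pou5f1 was at 10.41 ± 0.05 with 4OHT and 10.40 ± 0.05 without, Sox2 at 10.72 ± 0.11 and 10.64 ± 0.01, and Nanog at 10.89 ± 0.08 and 10.91 ± 0.03. Klf4 differed by 0.20 (SE 0.15; limma, adjusted p = 0.961), with both 4OHT arrays above both untreated arrays. The 95% intervals of the differences for Pou5f1, Sox2 and Nanog ran from -0.30 to 0.33, from -0.24 to 0.40 and from -0.38 to 0.33 on the log2 scale. The estrogen receptor genes were near background: Esr1 was at 3.99 ± 0.16 with 4OHT and 3.99 ± 0.02 without, and Esr2 was not above the background level in either group. Fkbp1a, which encodes the protein from which the FKBP domain is derived, differed by 0.03 (SE 0.15).

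The gene with the smallest p in 4OHT against untreated was Abca1 (probe set 10512949), which encodes a transporter that exports cholesterol from cells. Its signal was 5.92 ± 0.15 with 4OHT and 4.92 ± 0.06 without, a log2 difference of 1.00 (SE 0.15, 95% interval 0.67 to 1.34), and both 4OHT arrays lay above both untreated arrays. It did not pass the adjustment (limma, adjusted p = 0.96; unadjusted p = 5.69e-05). Among the other positive differences were those of Cfap77, a ciliary protein gene, at 1.12 (SE 0.22), Nova2, a neuronal splicing factor, at 0.73 (SE 0.16), and Tfap2a, a transcription factor of ectoderm and neural crest, at 0.65 (SE 0.14). Olfr401 (0.85), Gm10603 (0.80) and Gm10677 (0.76) were also among them, and Cela3a, Gckr and Olfr983 were not above background in either group. The largest negative statistics belonged to Moxd1 (-1.03, SE 0.17), Tnnt1, the slow skeletal muscle troponin T (-0.80, SE 0.14), and Ubxn11 (-0.77, SE 0.14). Stc2, which encodes the secreted glycoprotein stanniocalcin 2, differed by -0.68 (SE 0.14), and Gch1, the first enzyme of tetrahydrobiopterin synthesis, by -0.84 (SE 0.19). Mael and Zglp1, both genes of germ cells, differed by -0.72 (SE 0.15) and -0.72 (SE 0.16). Snord118 (-0.85), Zc3h6 (-0.70, and -0.37 on its dimmer probe set) and Arrdc4 (-0.64) were lower too. Cfap77 and Tfap2a in untreated cells and Moxd1 and Ubxn11 with 4OHT were below the background level of 3.73, which limits the size of these differences.

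No gene passed in 4OHT against untreated: limma called 0 of 19938 genes after Benjamini-Hochberg adjustment, and 995 had an unadjusted p under 0.05 (513 higher and 482 lower), where chance gives 997. The 95% interval of the difference lay within 2-fold for 19706 genes (98.8%) and within 1.5-fold for 72.1%. Here and in the other comparisons, the intervals are per gene and not adjusted for the number of genes. Of the 19938 genes, 12815 lay above background, and differences of the others are limited by it. The 2 arrays of each group did not overlap at 37.7% of genes, where chance gives 33.3%. The count of genes with unadjusted p under 0.05 depended on the fit. It lay above the 997 of chance with only the 2 groups compared fitted, and with array weights. The smallest adjusted p was then 0.403 and 0.423 (limma), against 0.96 in the primary analysis. With centring on the 75th percentile, or the replicate number as a block, the count lay below 997. Genes are not independent replicates, so such an excess alone shows no effect of 4OHT.

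**Figure D1:**
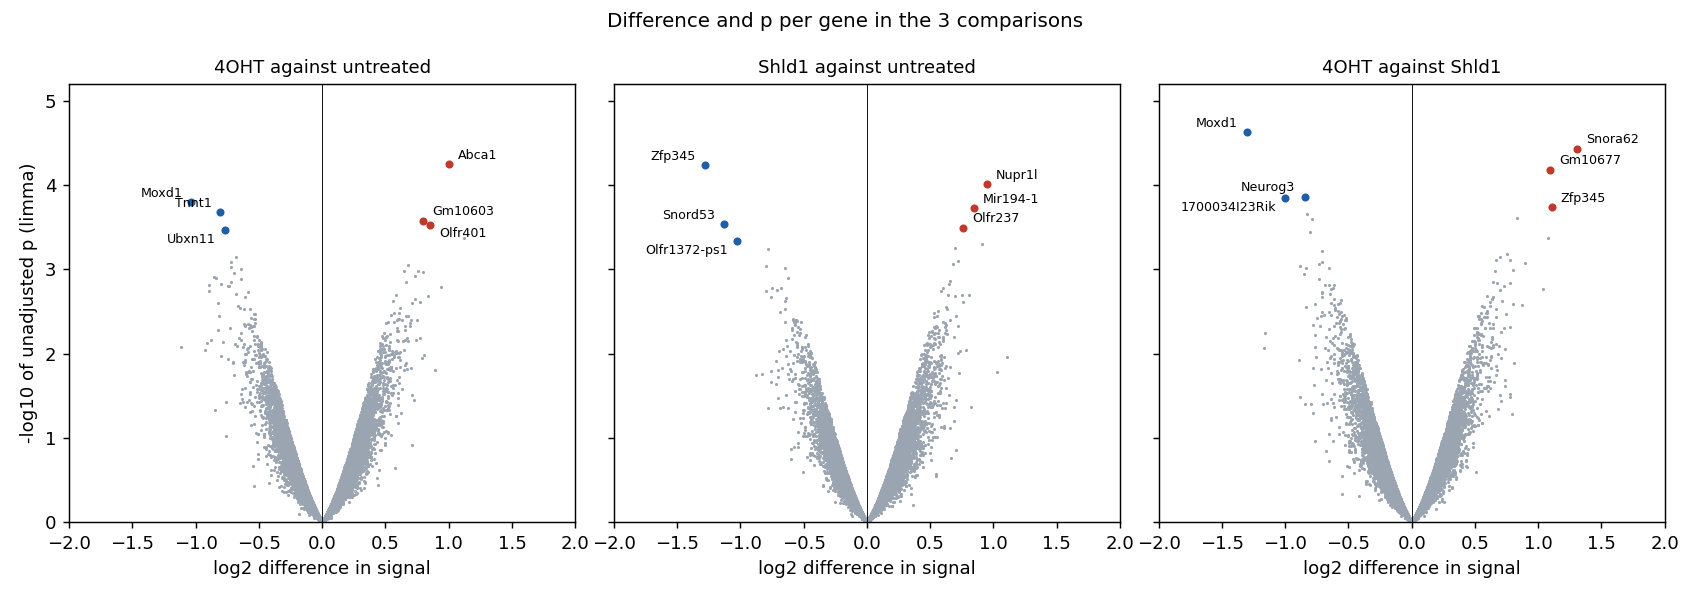
Each point is 1 of 19938 genes, with the log2 difference in signal on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis, for 4OHT against untreated, Shld1 against untreated and 4OHT against Shld1. Labelled are the 3 genes per direction with the smallest p, red higher and blue lower in the group named first; 0 genes passed the adjusted threshold in any panel.

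As a group, genes of cholesterol synthesis were lower with 4OHT. Of 20 measured genes, 19 were lower, with a median log2 difference of -0.32, and the list passed camera at the preset correlation (adjusted p = 3.89e-09; adjusted p = 0.82 with an estimated correlation). Idi1, an isomerase of the isoprenoid branch, was at 7.19 ± 0.15 with 4OHT and 7.68 ± 0.11 without (difference -0.49, SE 0.15), Hsd17b7 differed by -0.47 (SE 0.15), and Fdps, farnesyl diphosphate synthase, by -0.41 (SE 0.15). No member passed when adjusted over all genes or adjusted over the list alone (0 genes in each case), and 9 had an unadjusted p under 0.05, all lower. The list mean was below that of untreated cells on both 4OHT arrays, by -0.36 on replicate 1, the array with the narrower range, and by -0.22 on replicate 2. Another 5 genes of the list had no probe set matched to 1 symbol and were not analysed here. Fatty acid synthesis genes, by contrast, had a median of 0.01 over 11 genes (adjusted p = 0.992), with Scd2 at 0.33 (SE 0.14) and Fads2 at -0.33 (SE 0.14).

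Genes of hypoxia and glycolysis were lower with 4OHT as a group, 19 of 20 with a median of -0.26 (camera, adjusted p = 1.53e-07; adjusted p = 0.82 with an estimated correlation). Bnip3, a mitophagy receptor, differed by -0.88 (SE 0.26) but its 4OHT arrays were far apart (7.96 ± 0.60, against 8.83 ± 0.04 untreated). Ddit4, an inhibitor of mTORC1 signalling, differed by -0.53 (SE 0.14) and Ndrg1 by -0.48 (SE 0.15). The list mean was -0.44 on 4OHT replicate 1 and -0.15 on replicate 2, relative to untreated. The 19 genes of the unfolded protein and amino acid stress response were also lower as a group, 17 of them, with a median of -0.15 (adjusted p = 0.00015; adjusted p = 0.82 with an estimated correlation). Ddit3, which encodes the stress factor CHOP, differed by -0.62 (SE 0.16), and Chac1 by -0.46 (SE 0.16); Ddit3 and Ddit4 were the 2 members that passed when adjusted over the list alone, against 0 over all genes. Ddit4 belonged to both lists. The mean of the stress list was -0.22 and -0.19 on the 4OHT arrays, relative to untreated, and 0.02 and -0.18 on the Shld1 arrays, so Shld1 replicate 2, the array with the narrowest range, lay nearly as low alone.

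Small nucleolar RNAs, a class of short noncoding RNAs that guide modification of other RNAs, were lower in 40 of 51 cases with a median of -0.21 (adjusted p = 8.13e-07; adjusted p = 0.82 with an estimated correlation). Snord118 (-0.85, SE 0.19) and Snord49b (-0.89, SE 0.21) passed when adjusted over the list alone, 2 genes against 0 over all genes. The list mean was -0.36 on 4OHT replicate 1 and -0.16 on replicate 2. G2 and M phase genes were lower in 16 of 18 cases (median -0.16; adjusted p = 0.00559, and adjusted p = 0.994 with an estimated correlation), led by Aurkb at -0.27 (SE 0.16). Their list mean was -0.23 on 4OHT replicate 1 and -0.06 on replicate 2. Germ line genes were lower in 10 of 11 cases (median -0.07; adjusted p = 0.0217, and adjusted p = 0.82 with an estimated correlation). Mael was the 1 germ line gene to pass when adjusted over the list alone, and Dazl differed by -0.47 (SE 0.18). FK506-binding protein and calcineurin genes were lower in 14 of 17 cases (median -0.14; adjusted p = 0.0296, and adjusted p = 0.963 with an estimated correlation), with Fkbp7 at -0.58 (SE 0.16). That list mean was -0.19 and -0.06 on the 4OHT arrays, and -0.17 on Shld1 replicate 2 alone, below the 4OHT mean of -0.13. The 300 microRNA precursors had a median of 0.03 (adjusted p = 0.0338, and adjusted p = 0.994 with an estimated correlation), at a median level of 2.86, below the background level.

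Without 4OHT replicate 1, the G2 and M phase, germ line, FK506-binding and microRNA calls were lost (adjusted p = 0.44, 0.0853, 0.44 and 0.832). The mean difference of the germ line list stayed close to its size, from -0.191 to -0.173, while the others shrank, from -0.143 to -0.058, from -0.127 to -0.064 and from 0.058 to 0.012. Without untreated replicate 2 the same 4 calls were lost (adjusted p = 0.114, 0.141, 0.0802 and 0.167), at means of -0.115, -0.152, -0.138 and 0.041. The germ line call was also lost without 4OHT replicate 2 (adjusted p = 0.0853, mean -0.21) and the FK506-binding call without untreated replicate 1 (adjusted p = 0.101, mean -0.117).

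The lists of pluripotent states did not pass with 4OHT. Naive pluripotency genes had a median of -0.01 over 17 genes (adjusted p = 0.969), with Gbx2 at 0.55 (SE 0.17) and Fgf4 at -0.43 (SE 0.17). Core pluripotency genes had a median of 0.07 over 12 (adjusted p = 0.177). Formative and primed genes had a median of 0.01 over 13 (adjusted p = 0.969), although Lef1 (-0.61, SE 0.17) and Otx2 (-0.54, SE 0.16) passed when adjusted over the list alone. The estrogen response list of 20 genes had a median of -0.01 (adjusted p = 0.992). Its 1 member to pass when adjusted over the list alone was Stc2, and Myc differed by 0.53 (SE 0.16). Markers of trophoblast (median -0.02; adjusted p = 0.992), endoderm (-0.02; adjusted p = 0.969), mesoderm (0.03; adjusted p = 0.092), neural cells (0.06; adjusted p = 0.686) and fibroblasts (0.11; adjusted p = 0.171) did not pass either.

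**Figure D2:**
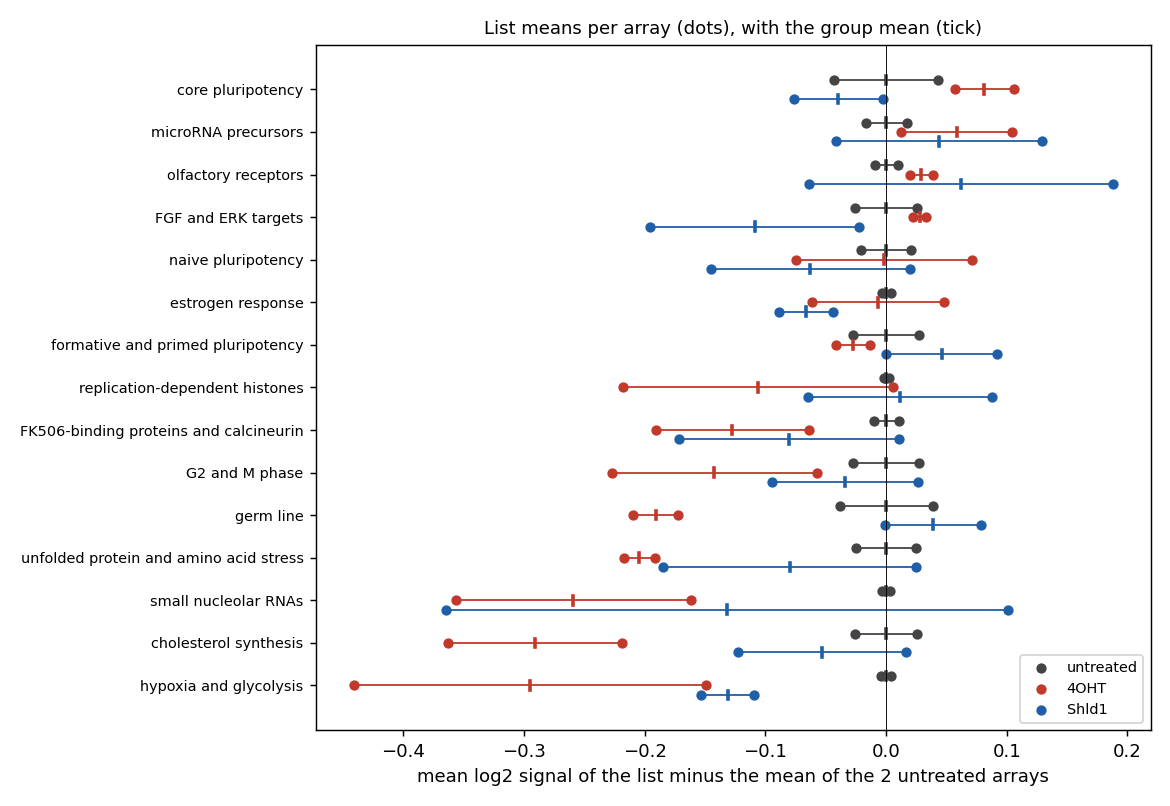
Dots give, for each array, the mean log2 signal of a gene list minus its mean over the 2 untreated arrays, and ticks give the group mean. Cholesterol synthesis genes lay at -0.36 and -0.22 on the 4OHT arrays and at 0.02 and -0.12 on the Shld1 arrays, while small nucleolar RNAs lay at 0.10 and -0.37 on the Shld1 arrays.

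With Shld1, neither the core factors nor Fkbp1a differed from untreated by more than the replicate spread. Pou5f1 was at 10.31 ± 0.11 with Shld1, Sox2 at 10.61 ± 0.09 and Nanog at 10.81 ± 0.25, with differences from untreated of -0.09 (SE 0.14), -0.04 (SE 0.14) and -0.10 (SE 0.16). Fkbp1a differed by -0.04 (SE 0.15, 95% interval -0.37 to 0.28), Klf4 by -0.02 (SE 0.15) and Esr1 by 0.16 (SE 0.18). The smallest p belonged to the zinc finger gene Zfp345 (probe set 10488465), at 2.79 ± 0.01 with Shld1 and 4.07 ± 0.23 without, a difference of -1.28 (SE 0.19; limma, adjusted p = 0.986). Nupr1l was at 6.22 ± 0.10 and 5.27 ± 0.18, a difference of 0.95 (SE 0.15), and the microRNA precursor Mir194-1 differed by 0.84 (SE 0.15). Rbmxl2 (0.69), Olfr237 (0.76), Plekhh3 (0.66), Scml4 (0.65) and Neurog3, a transcription factor of endocrine pancreas (0.60), had the next largest positive statistics above background. Adam34l, Vmn1r22 and 1700019A02Rik were below it. Olfr237 only just reached the level, at 3.726 with Shld1. It is among the olfactory receptor genes that set the level, as are Olfr401, Olfr1347 and Olfr1510. On the negative side were Snord53 (-1.13, SE 0.21), the retrovirus restriction gene Fv1 (-0.78, SE 0.16), Olfr1347 (-0.75), Timm21, a subunit of the mitochondrial import machinery (-0.71, SE 0.17), Tspear (-0.64), and Ddc, aromatic amino acid decarboxylase (-0.63, SE 0.14). Olfr1372-ps1, Cyp2d11 and 5730596B20Rik were not above background. Zfp345, Snord53, Fv1 and Tspear with Shld1 and Olfr237 and Scml4 in untreated cells were below the level of 3.73, so the size of these differences is limited by background.

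Limma called 0 of 19938 genes in Shld1 against untreated, and 866 had an unadjusted p under 0.05 (480 higher and 386 lower), where chance gives 997. The 95% interval lay within 2-fold for 19684 genes (98.7%) and within 1.5-fold for 74.3%. The arrays of the groups did not overlap at 32.5% of genes, with 33.3% by chance.

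Of the gene lists, 3 passed camera in this comparison. Hypoxia and glycolysis genes were lower in 17 of 20 cases with a median of -0.12 (adjusted p = 0.0362; adjusted p = 0.897 with an estimated correlation). Ankrd37 differed by -0.46 (SE 0.15) and Car9, carbonic anhydrase 9, by 0.38 (SE 0.15). Small nucleolar RNAs were lower in 35 of 51 cases with a median of -0.13 (adjusted p = 0.0204; adjusted p = 0.897 with an estimated correlation), and Snord53 was the 1 that passed when adjusted over the list alone. The olfactory receptor genes, which serve as background, were higher in 618 of 1015 cases with a median of 0.06 (adjusted p = 0.0362; adjusted p = 0.897 with an estimated correlation). Shld1 replicate 2, the array with the narrowest range, had a median olfactory receptor signal of 2.57, against 2.31 to 2.40 on the other arrays. Without that array the small nucleolar RNAs (adjusted p = 0.25) and the olfactory receptors (adjusted p = 0.0767) no longer passed and their direction turned. Both calls were also lost without untreated replicate 1 (adjusted p = 0.0797 for each), and the olfactory receptor call without untreated replicate 2 (0.256) or either 4OHT array (0.0558). The hypoxia call was lost when any single untreated or Shld1 array was left out (adjusted p = 0.0767 to 0.185), though its mean difference stayed at -0.109 to -0.153, against -0.131 with all arrays. It was kept without both arrays of narrower range (adjusted p = 0.027, mean -0.153). Cholesterol synthesis genes had a median of -0.04 (adjusted p = 0.45), and FK506-binding protein and calcineurin genes of -0.06 (adjusted p = 0.249), with Ppp3ca, a catalytic subunit of calcineurin, at -0.41 (SE 0.14). Naive, core and formative pluripotency genes had medians of -0.10, -0.06 and 0.05 (adjusted p = 0.416, 0.643 and 0.643).

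The agents were then set against each other, at the same dose of 1 µM. Abca1 was at 5.92 ± 0.15 with 4OHT and 5.09 ± 0.10 with Shld1, a difference of 0.83 (SE 0.15; limma, adjusted p = 0.555). Moxd1, which encodes a monooxygenase, had the smallest p, at 3.18 ± 0.004 with 4OHT and 4.49 ± 0.26 with Shld1 (-1.31, SE 0.17; adjusted p = 0.37). The small nucleolar RNA Snora62 differed by 1.31 (SE 0.18, adjusted p = 0.37), Zfp345 by 1.11 (SE 0.19), and the noncoding genes Gm10677 and Gm10603 by 1.10 (SE 0.17) and 0.70 (SE 0.14). Gm15348 (1.08), Olfr1510 (0.89), Prp2 (0.78) and Zfp111 (0.75) were the other positive genes above background. Moxd1 with 4OHT, and Zfp345 and Olfr1510 with Shld1, were below the background level of 3.73, which limits the size of their differences. Negative differences were found for Gch1 (-0.88, SE 0.19), Neurog3 (-0.85, SE 0.14), Tnnt1 (-0.79, SE 0.14), Morn2 (-0.73, SE 0.16) and the endonuclease gene Mus81 (-0.71, SE 0.14); Tlr6, Mlf1, Vmn1r22, Rnu5g and 1700034I23Rik were not above background in either group. Limma called 0 of 19938 genes and 1117 had an unadjusted p under 0.05 (499 higher and 618 lower), with 997 by chance. An intensity trend in the moderation gave 1 call, Snora62 (adjusted p = 0.0304). The 95% interval lay within 2-fold for 98.5% of genes.

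Between the agents, 6 lists passed camera. Cholesterol synthesis genes were lower with 4OHT than with Shld1 in 20 of 20 cases, with a median of -0.20 (adjusted p = 3.32e-06; adjusted p = 0.977 with an estimated correlation). Idi1 differed by -0.46 (SE 0.15), Msmo1 by -0.46 (SE 0.17) and Lss, lanosterol synthase, by -0.47 (SE 0.18), and 0 members passed when adjusted over the list alone. Germ line genes were lower in 9 of 11 cases (median -0.23; adjusted p = 0.00465, and adjusted p = 0.977 with an estimated correlation), with Mael at -0.48 (SE 0.15) and Dazl at -0.49 (SE 0.18). Targets of FGF and ERK signalling were higher in 11 of 15 cases (median 0.07; adjusted p = 0.0461, and adjusted p = 0.977 with an estimated correlation). That call was also lost without either untreated array, either 4OHT array or Shld1 replicate 2 (adjusted p up to 0.677). Its mean of 0.137 shrank to 0.05 without Shld1 replicate 2, grew to 0.223 without Shld1 replicate 1, and stayed at 0.131 to 0.142 in the other losses. Spry4 (0.53, SE 0.14), Etv4 (0.53, SE 0.15) and Dusp6 (0.53, SE 0.16) were the 3 members that passed when adjusted over the list alone. Hypoxia and glycolysis genes (median -0.18; adjusted p = 0.0241), unfolded protein and amino acid stress genes (-0.14; adjusted p = 0.0461) and replication-dependent histones (-0.13; adjusted p = 0.0461) were lower, each with adjusted p = 0.977 at an estimated correlation. The hypoxia difference rested on 4OHT replicate 1: without that array adjusted p = 0.958 and the mean went from -0.164 to -0.018. It was also lost without Shld1 replicate 1 (adjusted p = 0.0839) or replicate 2 (adjusted p = 0.0706), at means of -0.186 and -0.142. The stress call was lost without any array other than Shld1 replicate 2 (up to 0.936), and the histone call without either untreated array, 4OHT replicate 2 or Shld1 replicate 1 (up to 0.991). The stress mean of -0.125 shrank to -0.02 without Shld1 replicate 1, went to -0.229 without Shld1 replicate 2, and stayed at -0.112 to -0.138 in the other losses. The histone mean of -0.118 went to -0.006 without 4OHT replicate 2, to -0.042 without Shld1 replicate 1, and was unchanged without either untreated array. In the other direction, it went to -0.23 without 4OHT replicate 1 and to -0.194 without Shld1 replicate 2. Without both arrays of narrower range, which leaves 1 array per agent, the histone mean was -0.306 and the stress mean -0.216. The FGF and ERK mean shrank to 0.045 in that setting. The hypoxia mean went to -0.31 without 4OHT replicate 2. Without Shld1 replicate 1 the germ line call was lost (adjusted p = 0.143), at a mean of -0.19 against -0.23. Small nucleolar RNAs did not pass as a list (adjusted p = 0.125), while 3 members did when adjusted over the list alone, Snora62 higher and Snord118 (-0.76) and Snord49b (-0.84) lower.

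**Figure D3:**
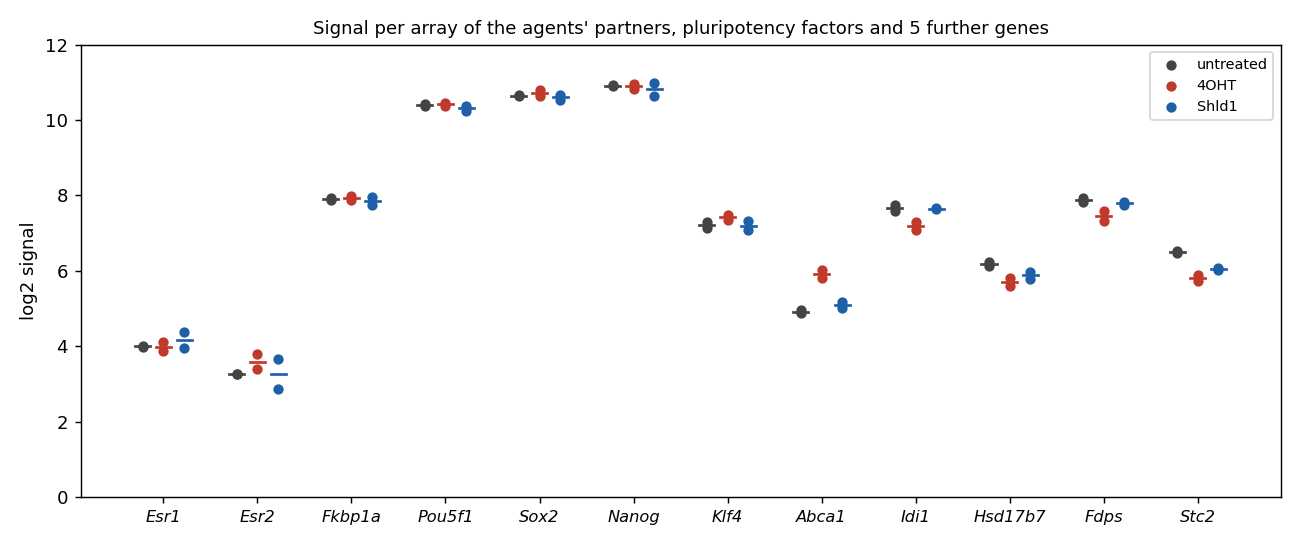
Dots give the log2 signal on each array and bars the mean of 2 arrays, for the agents' partners (Esr1, Esr2, Fkbp1a), pluripotency factors (Pou5f1, Sox2, Nanog, Klf4) and Abca1, Idi1, Hsd17b7, Fdps and Stc2. Abca1 lay at 5.92 on average with 4OHT, against 4.92 untreated and 5.09 with Shld1.

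Across genes, the differences from untreated with 4OHT and with Shld1 correlated at Pearson's r = 0.452 (Spearman's rho 0.441); genes are not independent replicates, and both comparisons share the untreated arrays. In 100 simulations of unchanged groups that shared 2 simulated untreated arrays, r averaged 0.500 and ran from 0.485 to 0.517. The covariance was 0.0161, against a simulated mean of 0.0147 and a highest simulated value of 0.0155, a difference of 0.00139 from the mean. The observed r lay below every simulated value, and the covariance above every one. However, the simulations gave a gene the same spread in all 3 groups and let genes vary independently. On the arrays, the SD of the replicate difference was 0.216 in untreated cells, 0.264 with 4OHT and 0.318 with Shld1. The simulated ranges are therefore no fair bound for these groups, and no conclusion is drawn from them. An unadjusted p under 0.05 in both comparisons was reached by 93 genes higher in both and 79 lower in both, and 5 genes went opposite ways. Unchanged groups sharing the untreated arrays gave 105 (79 to 138), 107 (82 to 131) and 1.63 (0 to 6) in 100 further simulations. These also assumed an equal spread in all groups, so they do not decide whether the shared arrays alone give as many genes moving together. With 2 untreated arrays, a split leaves 1 for each agent: r was 0.1015 with replicate 1 for 4OHT and replicate 2 for Shld1, and 0.08696 the other way round. The covariances were 0.004768 and 0.004134. No array is shared in these splits, so sharing does not account for these small positive values. However, each drug group held 1 of the 2 arrays of narrower range, and the splits were not run without them. The values therefore do not tell a common response to the agents from a common difference in range.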

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

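Cyclic loess normalization, leaving out 4OHT replicate 1 with Shld1 replicate 2, and a different untreated array for each agent were chosen after seeing the data; the other alternatives were fixed beforehand. Counts of called genes stayed at 0 in both comparisons with untreated cells under every alternative run, and Abca1 (4OHT against untreated) kept a difference of 0.90 to 1.11 with adjusted p from 0.402 to 1. In 4OHT against Shld1, an intensity trend gave 1 gene, with or without robust moderation: Snora62, at adjusted p = 0.0304 and 0.0305. An estimated correlation and fry, which tests another null hypothesis, each left 0 of the 8, 3 and 6 list calls. Leaving out each array in turn gave 4 to 8 calls for 4OHT against untreated, 0 to 7 for Shld1 against untreated and 3 to 9 for 4OHT against Shld1; a lone array is then assumed to vary like the other groups. For Shld1 against untreated, leaving out the dimmest 40% of genes, cyclic loess, and leaving out untreated replicate 1 or Shld1 replicate 2 each gave 0, and leaving out both narrow arrays 1. In 4OHT against untreated, cyclic loess lost the G2 and M phase, FK506-binding and microRNA calls (adjusted p = 0.129, 0.178 and 0.247). Leaving out the dimmest genes lost the FK506-binding call there and the stress and histone calls between the agents. With single arrays left out, adjusted p in Shld1 against untreated ran from 9.22e-09 to 0.25 for small nucleolar RNAs and from 8e-09 to 0.256 for olfactory receptors. Small nucleolar RNAs turned higher with Shld1 without Shld1 replicate 2 (adjusted p = 0.25) and without both narrow arrays (0.387). Olfactory receptors turned lower without Shld1 replicate 2 (0.0767), with cyclic loess (0.924) and without both narrow arrays (0.0636). The hypoxia list in 4OHT against Shld1 turned without both narrow arrays (0.967). The causes were not tested. The correlation of the differences (0.452) became 0.416 with quantile normalization, 0.426 without the dimmest genes, 0.424 with cyclic loess, 0.252 without both narrow arrays and 0.244 to 0.604 with single arrays left out. It became 0.1015 and 0.08696 with a different untreated array for each agent (4OHT against replicate 1 and against replicate 2). Fewer arrays change the noise the comparisons share. The replicate numbers gave no sign of pairing: replicate differences correlated at 0.0496, -0.0789 and -0.194 between groups. The labels name no shared day or batch, and these values cannot exclude one. The replicate block gave 0 genes in each comparison, 8, 3 and 3 lists, and the same correlation of 0.452. In 4OHT against Shld1 it did not call the stress, FGF and ERK and histone lists (adjusted p = 0.0569 each). Of 19938 genes, 12815 lay above background, and differences of the others are limited by it.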

Other observations

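The 15618 probe sets outside the genes tested (several symbols, none given, or a dimmer probe set of a gene) held no call in any comparison with limma over every probe set: 0 passed, and 970, 1096 and 1251 had an unadjusted p under 0.05 in 4OHT against untreated, Shld1 against untreated and 4OHT against Shld1, where chance gives 781. Probe sets are not independent replicates, so the excess alone shows no effect of an agent, and its cause was not tested. Genes of the lysosome had a median difference of -0.12 with 4OHT (18 genes; adjusted p = 0.092), with the sialidase gene Neu1 at -0.40 (SE 0.14). Xenobiotic metabolism genes had a median of 0.11 (adjusted p = 0.0725). Ribosomal protein genes had a median of 0.00 over 58 genes (adjusted p = 0.969), p53 targets of -0.04 (adjusted p = 0.472), heat shock genes of 0.02 (adjusted p = 0.969) and interferon response genes of 0.02 (adjusted p = 0.992).

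In what follows, the count of array pairs, the hypoxia test, and the readings of the LXR and hypoxia lists without the arrays of narrower range were tests chosen after the results were seen. The hypoxia reading was first that a difference of the untreated arrays was excluded, and was changed to open after the test without those arrays.

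A first hypothesis is that 4OHT shifted sterol balance in these cells, since Abca1 had the smallest p and cholesterol synthesis genes were lower as a group. Genes of like brightness moved less: 10000 random lists matched on signal had a middle 95% from -0.14 to 0.001, and 0% were as low as -0.29. Without the 2 arrays of narrower range 0% were as low as -0.22, but this leaves 1 4OHT array. The list thus lay below genes of like brightness, also on the 4OHT array without the narrower range. It had already passed camera on these arrays, so the percentiles are no separate support. Random genes were drawn independently, while the list's correlation was estimated at 0.23, so the random spread is understated. If the nuclear receptor LXR, which drives Abca1, were active, its other targets should be higher. The mean of 10 of them, 0.08, lay at percentile 98.3, above the upper end of the middle 95% of matched lists (0.07). That bound was set before the test was run, but the LXR list was not among the 33 fixed lists. The hypothesis arose from Abca1, and the LXR list shares Scd1, Scd2 and Srebf1 with the fatty acid list. Without the arrays of narrower range the mean of the 10 targets lay at percentile 79.3, inside the middle 95%. Of the 10, 7 were higher and 3 lower, with 1 in each direction under an unadjusted p of 0.05, Scd2 (0.33, SE 0.14) and Lpcat3 (-0.50, SE 0.16), and Abcg1 was at -0.095 (SE 0.16), so the LXR reading stays open. Variation between single arrays cannot be told apart from an effect either, since the 4OHT pair was the lowest of the 15 pairs of arrays (1 of 15) and no pair could give a share under 0.05; the call was also lost with an estimated correlation (adjusted p = 0.82).

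Hypoxia and glycolysis genes were lower with both agents, at a mean of -0.30 with 4OHT and -0.13 with Shld1, so a difference of the untreated arrays from both drug groups is a candidate explanation. If that were the whole cause, 4OHT and Shld1 should not differ; 0% of matched random lists were as low as the list in 4OHT against Shld1 (-0.16). That difference rested on 4OHT replicate 1: without the 2 arrays of narrower range the mean was 0.00, at percentile 72.6. The explanation therefore stays open, and oxygen or cell density in the cultures was not tested.

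Small nucleolar RNAs were lower with 4OHT by a mean of -0.26, but the 2 Shld1 arrays differed from each other in the same list by 0.466. Variation between single arrays could therefore produce a shift of this size, and the 2 untreated arrays, which differed by 0.007, do not show its full extent. Whether recovery of short RNAs differed between extractions was not tested.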
